A study of Mus musculus with 66 samples.

How the data were processed

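RNA from whole mouse cerebellum was hybridised to Illumina bead arrays, which carry many gene probes on each array and several arrays on each chip. The series holds 66 arrays: 35 from C57BL/6J and 31 from DBA/2J, both inbred strains. Per the labels, ages run daily from embryonic day 12 (E12) and then every 3 days from birth (P0) to P9, giving 23 groups of strain and age. Each group has 3 arrays, except C57BL/6J E14 with 2 and DBA/2J P9 with 1, and DBA/2J has no E19. The labels call the replicates biological. How many cerebella were pooled in a sample, and the sex of the mice, are not given in the sources used here.

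The authors deposited 1 signal table per strain, whose unit is intensity per the file headers: the average signal of each of 46632 probes, on a linear scale. The tables used here hold no detection p-values and no control probes. How the authors made these values is not given in the sources used here. Array medians ran from 78.6 to 88.6 in the C57BL/6J table and from 87.5 to 96.1 in the DBA/2J table, and arrays of the same chip differed in level between the tables, so a normalization within each table is an inference from the values. The authors also deposited a matrix whose unit is a score: on every array the values have mean 8 and SD 2, and they equal, within 0.006, 2 times the z-score plus 8 of the log2 of the signal plus an offset. That offset is 1.0 in C57BL/6J and 3.96 in DBA/2J, where the lowest signal is -2.96, so the transformation differs between the tables. A score difference is not a log2 fold change, and this matrix was used only as an alternative.

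The plan fixed before the data were examined called for detection p-values, or for background correction on raw values. The authors name these signals raw, but the tables gave no detection p-values and a normalization within each table was inferred. On that inference the plan's fallback for normalized tables was used: no further background correction, joint quantile normalization of all 66 arrays, and log2. The quantile step removes the difference in level between the tables but cannot remove a probe-specific difference between them. No background was subtracted here, and whether it was subtracted before deposition is not known. The fold changes of dim probes may therefore be understated. A probe was kept if it lay above its array's median on every array of at least 1 group with 2 or more arrays, which left 26645 probes; after normalization the array median was 6.44 on the log2 scale. Symbols were matched to the RefSeq mouse annotation for names only (26307 probes by symbol and 7973 through an older symbol). For 12352 probes the name in the files was kept. The files name no genome build, and no coordinates are given. For gene counts and gene lists the detected probe with the highest mean represented each of 14017 genes.

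A linear model with 1 mean per group was fitted to each probe in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with moderated tests on 43 residual degrees of freedom before moderation and Benjamini-Hochberg adjustment over all 26645 probes. A probe was called at an adjusted p under 0.05, and tests of single contrasts were two-sided. The comparisons were E18 against E12, P0 against E18 and P6 against P0, each as the equal-weight mean of both strains; the effect of age within each strain (F-test); DBA/2J minus C57BL/6J averaged over the 10 ages with replicates in both; the strain-by-age interaction (F-test); and the strain difference in the embryonic and in the postnatal change. Changes are log2 differences with the model's SE. Residuals of arrays from the same chip correlated (mean r = 0.294 over 90 pairs across groups), so fits with the chip or the array series as a block were among the alternatives; an array series is a set of chips whose numbers in the labels begin alike. There are 19 chips in 7 such series. Arrays of 1 age and 1 replicate number from both strains did not correlate reliably (mean r = 0.109 over 29 pairs, lowest -0.568), so replicate numbers were not taken to pair samples. The number of arrays limits the precision of every value.

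Gene lists were also fixed before the data were examined: cell cycle, ventricular zone and radial glia, granule cell progenitor, granule neuron, Purkinje cell, cerebellar nuclear and early rhombic lip neuron, GABAergic progenitor and interneuron, Bergmann glia and astrocyte, oligodendrocyte and myelin, synapse, Sonic hedgehog (SHH) signalling, choroid plexus, blood, microglia and macrophage, endothelial and pericyte, meninges and fibroblast, caudal hindbrain Hox, midbrain and brainstem nuclei, immediate early and dissection stress, sex-linked, and known C57BL/6J and DBA/2J variants. Of these 21 lists, 19 had at least 5 measured members and were tested with camera in limma, at a preset correlation between genes of 0.01 and again with the correlation estimated for each list. Adjusted p-values of lists cover the lists of 1 comparison. Genes were named by a rule set at the same time. For each change over age it takes the 6 largest rises and 6 largest falls among called genes with the same sign in both strains. For the strain difference it takes the 8 highest and 8 lowest with the same sign at all 10 ages, and the list of known variants; for the interaction, the 8 genes with the lowest p. From each list it takes up to 3 called members with the largest change, and members that moved against their list may be named. Some genes that this rule selects are not reported here.

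Alternatives set in advance were another offset (16) before the logarithm, the deposited score matrix, normexp background correction with offset 50, scaling to equal medians with a floor of 16, no filter, a stricter filter, a variance trend with robust moderation, array weights, the chip as a random or a fixed block, the array series as a fixed block, a block by replicate number, 1 strain alone, embryonic or postnatal ages alone, the compared groups alone, and leaving out each array in turn. A fit without 3 doubted arrays was added after the data were seen. Each comparison was also repeated on 100 splits of its arrays, the real one included. The fit was tested on simulated data: known changes were added to normal noise with each probe's own residual SD and no chip effects, so the shares called there are upper limits. Of 50 simulated probes changed by 1 on the log2 scale, 94% were called for the embryonic change, 96% for the perinatal and postnatal changes, 100% for the strain difference and 56% for the interaction. Figures were drawn in matplotlib 3.10.9 with pandas 2.3.3 and Python 3.11.15.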

Results

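Transcript levels were measured in whole cerebellum of C57BL/6J and DBA/2J mice across embryonic and early postnatal development. C57BL/6J was sampled at 12 ages and DBA/2J at 11, with 3 arrays per strain and age except C57BL/6J E14 (2 arrays) and DBA/2J P9 (1 array). The sampling addresses how cerebellar gene expression changes over these ages and whether the time course differs between the strains. Signals had array medians of 78.6 to 96.1, and the highest signal on an array lay between 11933 and 51615. Arrays of the same group correlated with r from 0.9413 to 0.9964 across probes, which are not independent replicates. Age changed 17730 of 26645 probes in C57BL/6J and 15973 in DBA/2J (limma F-tests, Benjamini-Hochberg adjusted). Changes below are log2 differences ± SE with 3 arrays per strain and age, and adjusted p-values come from limma with the Benjamini-Hochberg method.

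Between E12 and E18 cell cycle and ventricular zone genes fell and synapse and Purkinje cell genes rose. Of 27 measured synapse genes 24 rose and 0 fell (25 rose when adjusted over the list alone). The beta-synuclein gene Sncb rose by 3.60 ± 0.19, the synaptic vesicle gene Sv2b by 3.36 ± 0.25 and the calcium/calmodulin kinase subunit Camk2b by 3.32 ± 0.16. Of 26 cell cycle genes 24 fell and 0 rose (25 fell when adjusted over the list alone), among them the kinetochore motor Cenpe, the mitotic kinase Plk1 and the chromosomal passenger gene Cdca8. Their changes were -1.60 ± 0.12, -1.51 ± 0.15 and -1.51 ± 0.14. Of 18 ventricular zone and radial glia genes 13 fell, 1 rose and 4 did not pass the test (14 fell when adjusted over the list alone). The progenitor surface gene Prom1 changed by -2.26 ± 0.11, the Notch target Hes5 by -2.17 ± 0.21 and the Notch ligand Dll1 by -1.92 ± 0.13, while Fabp7, a radial glial fatty acid binding protein, rose. With the array series or the chip as a fixed block 0 members of this list rose past the test. The list tests gave adjusted p = 3.58e-12 for synapse, 2.22e-12 for cell cycle and 9.11e-08 for ventricular zone. With an estimated correlation they gave adjusted p = 0.00188, 0.00188 and 0.000135.

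Of 19 Purkinje cell genes 12 rose, 4 fell and 3 did not pass (12 and 4 when adjusted over the list alone; list adjusted p = 0.000681, and 0.0214 with an estimated correlation). The aldolase gene Aldoc, a marker of Purkinje cell stripes, rose by 3.56 ± 0.20 and the nuclear receptor Rora by 3.53 ± 0.26. The members that fell were Bcl11a, Lhx5, Pcp2 and Ppp1r17. With the array series as a block 11 members rose and 1 fell, so most of these falls lost their call. With the chip as a fixed block 11 rose and 2 fell. Of 18 granule neuron genes 10 rose and 1 fell (11 and 1 when adjusted over the list alone), with adjusted p = 0.000924, but 0.108 with an estimated correlation. Cntnap4 rose by 3.29 ± 0.14 and the calretinin gene Calb2 by 2.96 ± 0.17, and the axonal adhesion gene Cntn2 fell. With the chip as a fixed block 0 members of this list fell past the test. Of 12 granule cell progenitor genes 8 rose and 1 fell (8 and 1 over the list alone), with adjusted p = 0.0317, or 0.163 with an estimated correlation. The patterning factor Pax6 rose by 1.98 ± 0.15 and the cyclin Ccnd2 changed by -1.06 ± 0.11. The list's adjusted p was 0.103 with the array series as a block.

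Of 12 cerebellar nuclear and early rhombic lip genes 3 rose and 6 fell (3 and 6 over the list alone), with adjusted p = 0.0198, but 0.126 with an estimated correlation and 0.104 with the chip as a block. The transcription factors Pou3f1 and Irx3 changed by -2.77 ± 0.12 and -2.41 ± 0.15, and Eomes, a factor of unipolar brush and nuclear neurons, rose by 2.24 ± 0.15. All 12 GABAergic progenitor and interneuron genes passed the test, 5 upward and 7 downward (5 and 7 over the list alone), and the list as a whole did not (adjusted p = 0.149). The progenitor factor Olig3 changed by -3.27 ± 0.09, the gap junction gene Gjd2 rose by 2.82 ± 0.17 and the somatostatin gene Sst by 2.76 ± 0.23. Of 18 endothelial and pericyte genes 11 rose and 2 fell (12 and 2 over the list alone), with adjusted p = 0.000847, or 0.126 with an estimated correlation. The pericyte regulator Rgs5 rose by 2.19 ± 0.18 and the blood-brain barrier transporter Slco1c1 by 1.93 ± 0.13. Of 11 blood genes 2 rose and 5 fell (2 and 5 over the list alone), with adjusted p = 0.00426, or 0.108 with an estimated correlation.

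The embryonic globins had the largest falls from E12 to E18: Hbb-y changed by -6.84 ± 0.31, Hba-x by -6.45 ± 0.25 and Hbb-bh1 by -5.67 ± 0.19. Hbb-y was near background by E18. The homeobox genes Dbx1 and Msx3 changed by -3.93 ± 0.22 and -3.89 ± 0.16 and the retinoic acid binding protein Crabp1 by -3.81 ± 0.20. Among the largest rises were the phosphatase subunit Ppp2r2c (4.01 ± 0.22), the calcium sensor Hpca (3.95 ± 0.18), the calcium binding gene Caln1 (3.87 ± 0.18), the matrix protein Tnc (3.84 ± 0.21) and the postsynaptic scaffold Dlg2 (3.74 ± 0.22). Another probe of Caln1 was called in the opposite direction.

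In all, 13121 probes differed between E12 and E18, 6073 higher and 7048 lower at E18, and 2142 changed at least 2-fold. Camera called 9 lists, 5 upward and 4 downward, of which 4 kept the call with an estimated correlation. E12 and E18 shared 0 chips and 0 array series, and with the series as a block the count was 8624, with 7165 of the main calls (54.6%) kept in the same direction. Every gene given above with its change passed the test with that block. The array labelled DBA/2J E12 replicate 2 carried transcripts of later ages: there the myelin gene Mbp stood at 12.21 on the log2 scale, against 7.47 to 8.12 on the other 5 E12 arrays. The oligodendrocyte and myelin list (8 of 19 rose, 2 fell; 8 and 2 over the list alone) and the Bergmann glia and astrocyte list (7 of 16 rose, 3 fell; 7 and 3 over the list alone) were not called with it, although the myelin list was under scaling to equal medians. Without it both were called at the preset correlation (adjusted p = 0.00479 and 0.0119) but not with an estimated one (0.172 and 0.125). The embryonic change of Mbp was -0.85 ± 0.36 (adjusted p = 0.0455) with this array and -0.17 ± 0.23 (adjusted p = 0.588) without.

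**Figure D1:**
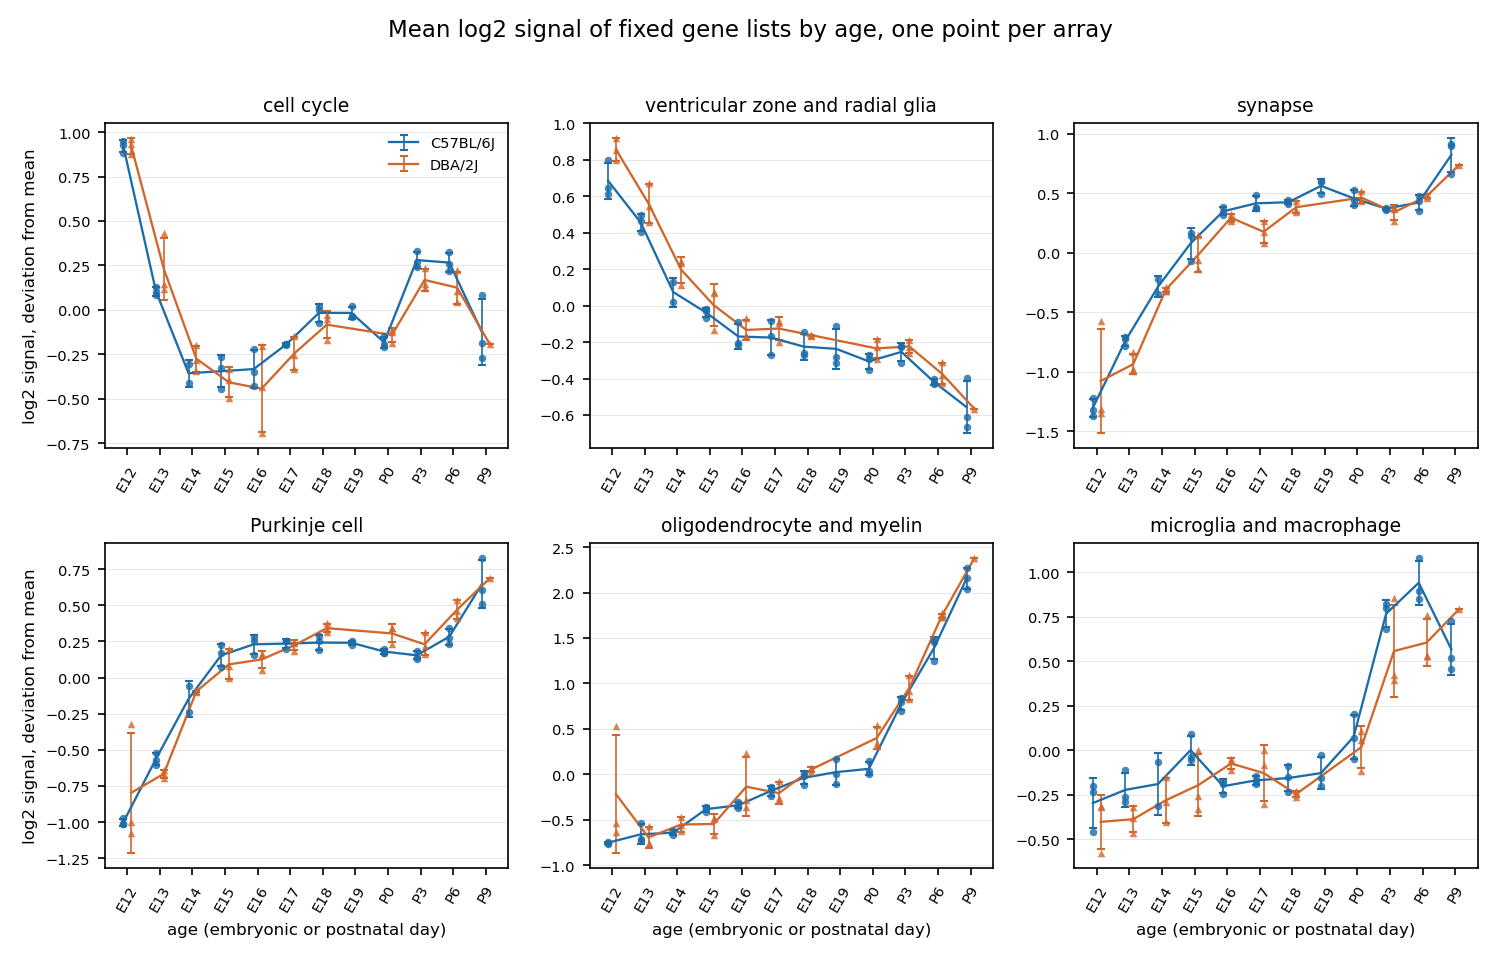
Mean log2 signal of the measured members of 6 fixed gene lists by age (x axis, embryonic or postnatal day, not spaced to scale), for C57BL/6J (circles) and DBA/2J (triangles). The y axis (log2) is the deviation from each gene's mean over the group means of the 10 shared ages in both strains. Each point is 1 array, lines join group means and bars are ± SD (no bar for the single DBA/2J P9 array). Cell cycle and ventricular zone genes were highest at E12, synapse and Purkinje cell genes lowest there, and myelin genes rose after birth; the raised DBA/2J E12 point in the myelin panel is replicate 2.

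Around birth, between E18 and P0, single glial and meningeal genes rose and adult-type globin genes fell, but no list was called with an estimated correlation. The astrocyte water channel Aqp4 rose by 2.19 ± 0.31, the matrix proteoglycan Dcn by 2.10 ± 0.25 and the metallothionein Mt1 by 2.06 ± 0.20. Arrdc4 rose by 2.11 ± 0.18, although another of its probes was called in the opposite direction, and the cerebellar transcription factor Zic2 rose by 1.92 ± 0.24. The adult beta-globin Hbb-b1 changed by -1.46 ± 0.15, the alpha-globin Hba-a1 by -1.10 ± 0.15 and the heme synthesis enzyme Alas2 by -0.71 ± 0.13. Of 10 other detected Hbb-b1 probes 1 was called in the opposite direction. The microRNA host gene Mir124a-1hg changed by -1.92 ± 0.24, Fbxo30 by -1.92 ± 0.21 and the sialyltransferase St8sia4 by -1.51 ± 0.16. The Purkinje cell transcription factors Foxp2 and Bcl11a changed by -0.78 ± 0.14 and -0.65 ± 0.13.

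Of 16 Bergmann glia and astrocyte genes 7 rose and 0 fell (8 and 1 when adjusted over the list alone), with Apoe, a lipid carrier of astrocytes, up by 1.17 ± 0.19. The list had adjusted p = 0.00789, but 0.541 with an estimated correlation and 0.26 with the array series as a block. Of 16 microglia and macrophage genes 8 rose and 1 fell (10 and 1 over the list alone), with the complement genes C1qc and C1qb up by 0.66 ± 0.10 and 0.54 ± 0.14. That list had adjusted p = 0.011, or 0.552 with an estimated correlation. Of 14 meninges and fibroblast genes 7 rose and 1 fell (7 and 1 over the list alone), with the transporter Slc6a13 up by 1.04 ± 0.14 and the growth factor Igf2 by 0.94 ± 0.16. That list had adjusted p = 0.00746, or 0.541 with an estimated correlation. The blood list (1 of 11 rose, 5 fell; 1 and 6 over the list alone) had adjusted p = 0.052, and its call turned in 22 of 80 settings (lowest adjusted p = 0.00971). Of 9 immediate early and dissection stress genes 3 rose and 1 fell (3 and 1 over the list alone; adjusted p = 0.222), with the activity-induced Egr1 up by 1.28 ± 0.17 and Fos by 0.48 ± 0.09.

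Several of the named changes at birth were lost with a block. The synaptic complexin Cplx2 rose by 1.77 ± 0.33 but had an adjusted p of 0.145 with the chip as a block. The tubulin gene Tuba1a changed by -2.07 ± 0.37 and the ubiquitin ligase Huwe1 by -1.51 ± 0.31, and with the series as a block neither passed (adjusted p = 0.0754 and 0.238). With the chip as a block both turned to the other sign, at 0.01 and 0.17, and Igf2 no longer passed, at 0.43 (adjusted p = 0.375). Hba-a1 no longer passed under scaling to equal medians (adjusted p = 0.0531).

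The perinatal comparison called 8672 probes, 4382 higher and 4290 lower at P0, of which 328 changed at least 2-fold, and 3 lists, all upward and 0 of them with an estimated correlation (1 of 19 lists then had an unadjusted p under 0.05). E18 and P0 shared 0 chips and 0 array series. With the chip as a fixed block 2544 probes were called. With the series as a block 4192 were called, and 2308 of the main calls (26.6%) kept call and direction, while the median ratio of the blocked change to the change without a block was 0.62. For the other called probes array series and age cannot be told apart. In C57BL/6J alone 5463 probes passed and in DBA/2J alone 1965; Dcn rose by 0.69 in C57BL/6J and 3.51 in DBA/2J.

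From P0 to P6 genes of myelin, astroglia, microglia, vessels and meninges rose together. Of 19 oligodendrocyte and myelin genes 13 rose and 1 fell (14 and 1 when adjusted over the list alone). Myelin basic protein, Mbp, rose by 4.41 ± 0.36 and the myelin claudin Cldn11 by 3.23 ± 0.30, and Mog fell. Of 16 Bergmann glia and astrocyte genes 10 rose and 0 fell (13 and 0 over the list alone), with the intermediate filament Gfap up by 3.91 ± 0.24, Aqp4 by 2.92 ± 0.31 and the connexin Gjb6 by 2.18 ± 0.17. Of 16 microglia and macrophage genes 13 rose and 0 fell (14 and 0 over the list alone), with the lysozyme Lyz2 up by 1.49 ± 0.10, the mannose receptor Mrc1 by 1.19 ± 0.12 and Laptm5 by 1.06 ± 0.12. Of 18 endothelial and pericyte genes 13 rose and 0 fell (15 and 0 over the list alone), with Vtn up by 1.35 ± 0.12. Of 14 meninges and fibroblast genes 10 rose and 1 fell (10 and 1 over the list alone), with the prostaglandin synthase Ptgds up by 4.55 ± 0.40 and Dcn by 2.51 ± 0.25. The adjusted p-values of these 5 lists were 1.32e-19, 5.30e-13, 2.44e-16, 9.12e-12 and 2.62e-13. With an estimated correlation they were 0.000665, 0.00102, 0.000743, 0.00133 and 0.000665.

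Of 26 cell cycle genes 14 rose and 0 fell from P0 to P6 (18 and 0 over the list alone; adjusted p = 8.32e-08, and 0.0139 with an estimated correlation), in contrast to their fall before birth. The proliferation marker Mki67 and the cyclin Ccnb1 rose by 0.66 ± 0.14 and 0.66 ± 0.16. Of 12 cerebellar nuclear and early rhombic lip genes 0 rose and 6 fell (0 and 7 over the list alone; adjusted p = 0.000246, and 0.0139 with an estimated correlation), with Irx3 at -0.95 ± 0.15, Eomes at -0.86 ± 0.15 and Pou3f1 at -0.77 ± 0.12. Of 12 granule cell progenitor genes 4 rose and 1 fell (4 and 2 over the list alone; adjusted p = 0.0167, but 0.122 with an estimated correlation), with Ccnd2 up by 1.16 ± 0.11. Of 18 granule neuron genes 7 rose and 3 fell (7 and 3 over the list alone; adjusted p = 0.0432, but 0.311 with an estimated correlation), with Cntn2 up by 1.30 ± 0.29 and the glutamate transporter Slc17a7 by 0.90 ± 0.15. Of 8 midbrain and brainstem genes 0 rose and 2 fell (0 and 2 over the list alone; adjusted p = 0.0432, but 0.311 with an estimated correlation), with Isl1 at -1.06 ± 0.13. The calls of these last 3 lists each ended under at least 1 alternative fit or without 1 array.

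The Purkinje cell list was not called after birth (adjusted p = 0.281; 5 of 19 rose and 3 fell, 6 and 3 over the list alone), but its members moved apart. The calcium buffer Pvalb rose by 1.80 ± 0.28 and the calcium release channel Itpr1 by 1.48 ± 0.20, whereas Foxp2 changed by -1.45 ± 0.14. In the ventricular zone list Nes, an intermediate filament of progenitors, changed by -1.17 ± 0.22. In the SHH list the secreted Wnt modulator Sfrp1 rose by 1.73 ± 0.17. Other large rises were the homeobox gene Otx1 (3.57 ± 0.22) and the oligodendrocyte phosphodiesterase Enpp6 (3.38 ± 0.14). The largest falls were the homeobox gene Gbx2 (-2.26 ± 0.12), the neuropeptide gene Cartpt (-1.86 ± 0.16), the RNA binding gene Igf2bp2 (-1.84 ± 0.13), Sst (-1.79 ± 0.23), the G-protein regulator Rgs4 (-1.70 ± 0.19) and Ccdc184 (-1.60 ± 0.17). The value of Cartpt is the mean of unlike changes, -3.07 in C57BL/6J and -0.65 in DBA/2J.

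The postnatal comparison called 3645 probes, 1899 higher and 1746 lower at P6, of which 221 changed at least 2-fold, and 10 lists, 8 upward and 2 downward, or 7 with an estimated correlation (6 and 1). P0 and P6 shared 2 chips. Within the chip that held C57BL/6J arrays of both ages (2 and 2 arrays) the median myelin change was 1.29, and within the chip with DBA/2J arrays (2 and 2) 1.30. For the other lists that rose together the median was larger in the C57BL/6J chip than in the DBA/2J chip. It was 0.77 and 0.5 for astroglia, 1.02 and 0.54 for microglia, 0.68 and 0.33 for vessels and 0.96 and 0.32 for meninges. Strain and chip cannot be told apart in these values, and the difference between the chips was not tested. In C57BL/6J alone 1996 probes passed and in DBA/2J alone 1323.

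Averaged over the 10 shared ages, DBA/2J differed from C57BL/6J at single genes in both directions. Higher in DBA/2J were the kelch gene Kbtbd11 (2.30 ± 0.17), the centrosomal gene Sfi1 (1.84 ± 0.08), the scavenger receptor Stab2 (1.82 ± 0.07), Gadd45gip1 (1.81 ± 0.07), Cuedc1 (1.71 ± 0.06), the secreted phosphoprotein Spp1 (1.52 ± 0.07) and the translation factor Paip1 (1.47 ± 0.08). Hbb-b2 stood 3.68 ± 0.16 higher, but the adult beta-globin genes are nearly alike in sequence, so which of them this probe measured is uncertain. Lower in DBA/2J were the lipase Abhd16a (-3.44 ± 0.14), Thumpd1 (-3.36 ± 0.13), the noncoding RNA Rmst (-3.04 ± 0.19), the ribosomal protein gene Rpl29 (-2.87 ± 0.13), Soga3 (-2.83 ± 0.09), the kinase Tesk1 (-2.83 ± 0.11), the caspase Casp9 (-2.80 ± 0.10) and the serpin Serpini1 (-2.69 ± 0.08). All of these passed limma's test at adjusted p-values of 6.78e-16 or lower, with the same sign at all 10 ages. Each value comes from 1 probe, and other probes of a gene often differed. Of 76 genes called at least 2-fold lower with another detected probe, the brightest other probe shared the sign in 43. It was called in that direction in 24. Of 11 such genes called higher these numbers were 7 and 5.

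Of 9 measured genes on the list of known variants 4 were higher, 3 lower and 2 not past the test (4 and 4 when adjusted over the list alone). The glyoxalase Glo1 stood 0.92 ± 0.05 higher in DBA/2J, the heme synthesis enzyme Alad 1.12 ± 0.04 and the GABA receptor subunit Gabra2 0.52 ± 0.05. The melanosome gene Gpnmb (-0.49 ± 0.04), the myosin Myo5a (-0.71 ± 0.07) and the mitochondrial transhydrogenase Nnt (-0.69 ± 0.04) were lower. Nnt carries a deletion in C57BL/6J, so the direction at this probe is opposite to a loss of the transcript in that strain. The complement gene Hc differed by -0.06 ± 0.03 (adjusted p = 0.126, or 0.0182 without 3 DBA/2J arrays of doubtful strain) and the pigmentation gene Tyrp1 by 0.00 ± 0.04 (adjusted p = 0.974). Among cell type genes, the immune receptor subunit Fcer1g was lower by -1.61 ± 0.07, the checkpoint kinase Bub1b by -0.77 ± 0.05 and the vesicular GABA transporter Slc32a1 by -0.65 ± 0.07, and the cyclin Ccnd1 was higher by 0.54 ± 0.06. Of 19 oligodendrocyte and myelin genes 6 were higher and 0 lower in DBA/2J (8 and 0 over the list alone), and the list did not pass (adjusted p = 0.0955, or 0.885 with an estimated correlation). It passed under scaling to equal medians and without DBA/2J E12 replicate 1 or 3 (lowest adjusted p = 0.0264). It did not with the chip as a block (0.789) or without E12 replicate 2, the array with later transcripts (0.143).

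The strain comparison called 4534 probes, 2187 higher and 2347 lower in DBA/2J, and 243 differed at least 2-fold, 52 higher and 191 lower. Under scaling to equal medians the balance was 1207 higher and 3122 lower (27.9% higher, against 48.2%), so the overall balance of directions depends on the scaling. The strains come from separate deposited tables, so a probe-specific difference between the tables is part of this comparison, and the deposited score matrix shares that limit. Within 13 pairs of chip and age that held both strains, the same sign was seen for 74.3% to 90.5% of called probes in every pair but 1. In that pair, with DBA/2J E13 replicate 3, it was 49.7%. The arrays of these pairs also entered the strain contrast, except for the P9 pair (1 array per strain), where the share was 78.3%. Camera called 0 lists for this comparison, with 2 of 19 at an unadjusted p under 0.05 (0 with an estimated correlation). It tests for a shift in 1 direction and says little of lists whose members go both ways, such as the known variants.

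The time course itself differed between the strains for 1063 probes (F-test), the gene with the lowest p being Gpnmb. Gpnmb rose after birth in C57BL/6J, to 8.75 ± 0.36 on the log2 scale at P6 (SD, n = 3), and stayed near background in DBA/2J, at 6.32 ± 0.05 (SD, n = 3). Prrt4, Cdkl2 and Sspn rose from E12 to E18 in C57BL/6J by 2.51, 2.69 and 1.09, against changes of -0.15, 0.38 and -0.36 in DBA/2J. At E18 in DBA/2J the Prrt4 probe (6.36 to 6.51) lay around the array median of 6.44 and the Sspn probe (6.02 to 6.14) below it, so a change there would not be resolved. The cell cycle inhibitor Cdkn2b was higher in DBA/2J at E12 by 1.33 ± 0.11 and lower at P3, at -0.69 ± 0.11. The lower strain lay close to the array median in both cases, C57BL/6J at 6.69 to 6.79 and DBA/2J at 6.54 to 6.67, so these differences may be cut short. The chemokine Ccl21a was higher in DBA/2J at P3 by 2.17 ± 0.19, Cartpt lower at P0, at -2.97 ± 0.23, and Spp1 higher at E16 by 3.42 ± 0.21. The C57BL/6J signals of Spp1 at E16 (6.52 to 6.82) were also close to the array median, so this difference may be larger. Adjusted p-values ran from 5.81e-14 for Gpnmb to 1.28e-09 for Spp1.

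The change from E12 to E18 differed between the strains for 54 probes, 19 more positive and 35 more negative in DBA/2J, with Cdkn2b at -1.72 ± 0.15, Prrt4 at -2.65 ± 0.25, Cdkl2 at -2.31 ± 0.28 and Sspn at -1.46 ± 0.20. At E18 the DBA/2J signals of Cdkn2b, Prrt4 and Sspn were near background. Cartpt differed by -2.25 ± 0.33, the adhesion molecule Vcam1 by 1.22 ± 0.19 and the peptide transporter Slc15a2 by 2.15 ± 0.38. The change from P0 to P6 differed for 19 probes, 7 more positive and 12 more negative in DBA/2J. Among these, Gpnmb differed by -1.96 ± 0.17, Cartpt by 2.42 ± 0.33, Slc6a13 by -1.88 ± 0.28, Dcn by -2.58 ± 0.50 and Prrt4 by 1.31 ± 0.25. The DBA/2J signals of Gpnmb at P0 and P6 (6.21 to 6.44), of Prrt4 at both (6.27 to 6.67) and of Cartpt at P6 (6.40 to 6.51) were near background, so changes there are cut short. Vcam1, Slc15a2, Slc6a13 and Dcn were chosen here after their values were seen. The interaction count depends on the arrays and on the processing: it was 2975 without the 3 doubted DBA/2J arrays, 698 without C57BL/6J E17 replicate 1, 609 under scaling to equal medians and 632 with the chip as a fixed block. The count of 54 was 31 without DBA/2J E12 replicate 2, 33 with the stricter filter and 106 with the chip as a random block. The count of 19 ran from 4 in the compared groups alone to 66 with the chip as a random block, array weights aside.

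**Figure D2:**
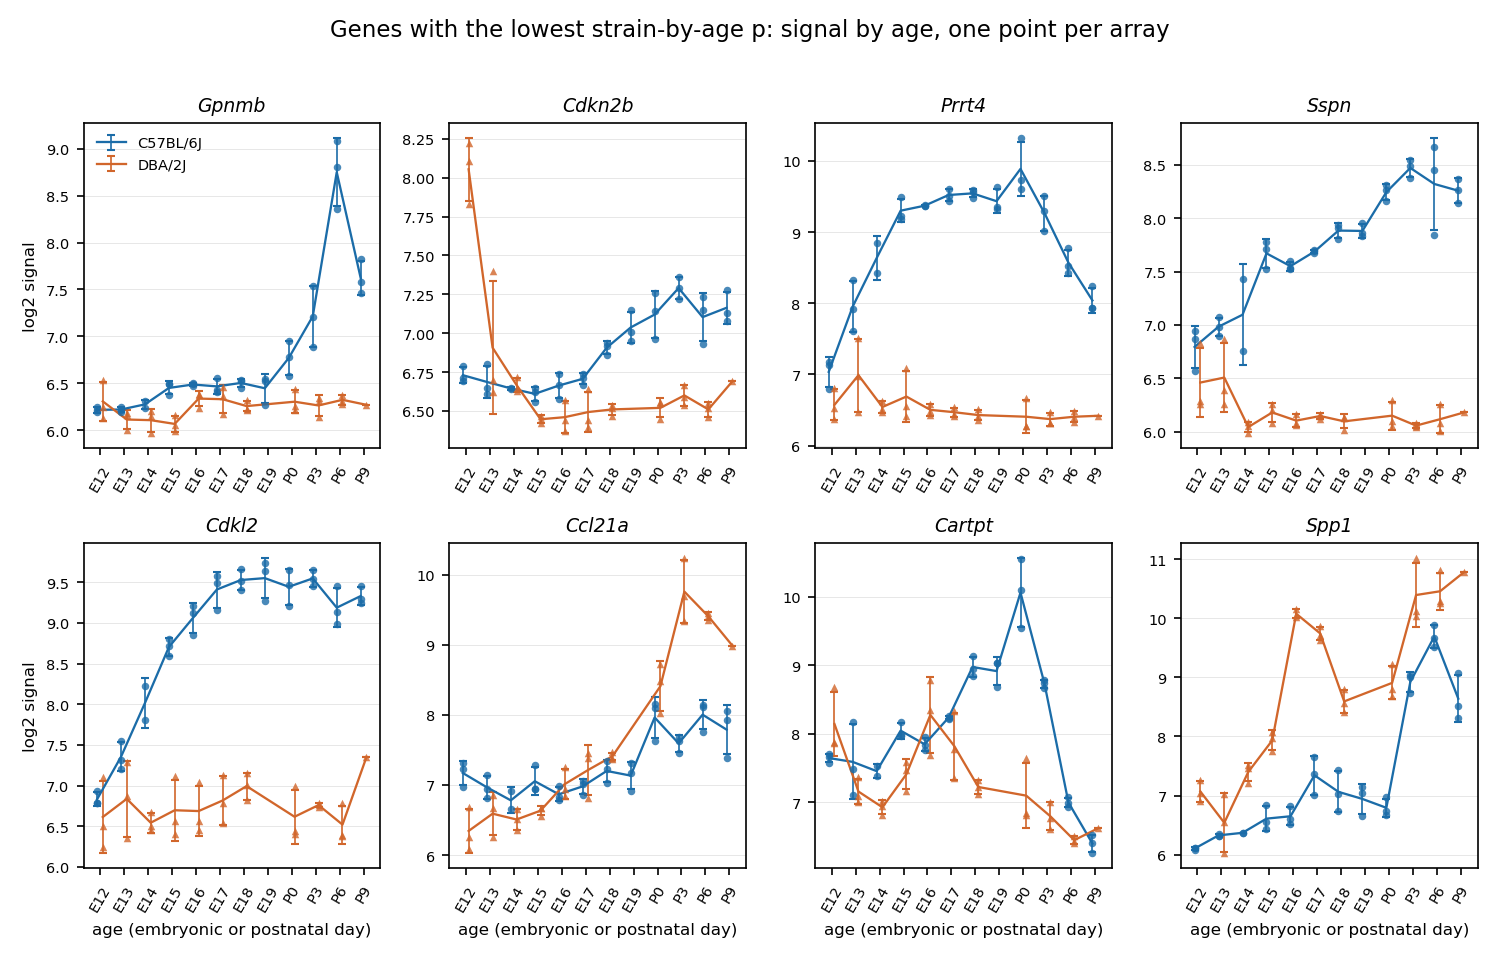
Log2 signal (y axis) by age (x axis, embryonic or postnatal day, not spaced to scale) of the 8 genes with the lowest strain-by-age p, in C57BL/6J (circles) and DBA/2J (triangles); each point is 1 array, lines join group means and bars are ± SD (no bar for the single DBA/2J P9 array). Gpnmb reached 8.75 at P6 in C57BL/6J and 6.32 in DBA/2J.

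Not every array labelled DBA/2J carried the DBA/2J pattern. At 793 to 893 probes with a strain difference at the other ages, each array was placed on a scale with 0 for the C57BL/6J arrays of its age and 1 for the mean DBA/2J difference. The 35 C57BL/6J arrays lay between -0.11 and 0.11 and 28 DBA/2J arrays between 0.85 and 1.15. The other 3, called the doubted arrays here, were E13 replicate 3 at -0.02, E13 replicate 2 at 0.41 and E12 replicate 2 at 0.59. At E13, where 2 of the 3 DBA/2J arrays are in doubt, 45 probes differed between the strains. The counts were 3186 at E16 and 3321 at E17, and 681 to 1339 at the remaining ages. Replicates 1 and 2 of DBA/2J E16 and E17 shared a chip, and whether this adds to the counts there was not tested.

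**Figure D3:**
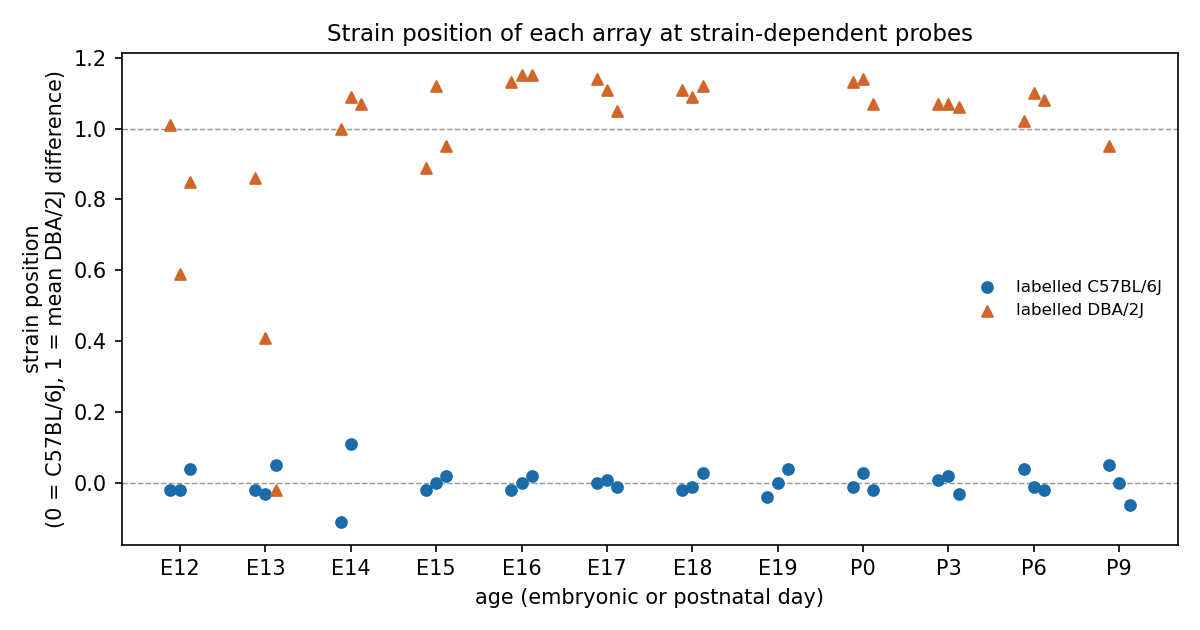
Strain position (y axis, no unit; 0 is the C57BL/6J level of the same age and 1 the mean DBA/2J difference) of each of the 66 arrays by age (x axis), for arrays labelled C57BL/6J (circles) and DBA/2J (triangles). The 3 triangles at -0.02, 0.41 and 0.59 are E13 replicate 3, E13 replicate 2 and E12 replicate 2, and the other DBA/2J arrays lie at 0.85 or above.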

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

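The tests of a weak strain difference, a chip effect, a label swap, RNA of a later age and the array series, the mixing computed on the signal scale, the balance of signs and its rescaled value, and the fit without the 3 doubted arrays, were chosen only after the result was seen.

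The F-test of the strain-by-age interaction passed for 1063 probes. It was lowest for Gpnmb (adjusted p = 5.81e-14), a gene known to carry a loss-of-function variant in DBA/2J. Cdkn2b followed (adjusted p = 8.65e-13), with Prrt4 (1.32e-12), Sspn (4.37e-11), Cdkl2 (9.4e-11), Ccl21a (9.4e-11), Cartpt (1.65e-10) and Spp1 (1.28e-09). Chance can be excluded for this count: 1 of 100 splits gave as many probes, the real one, and the highest other gave 152. The strain difference in the embryonic change passed for 54 probes, where 1 of 100 splits gave as many, the real one, and the highest other gave 19. The strain difference in the postnatal change passed for 19 probes, and there chance cannot be excluded, since 17 of 100 splits gave as many. Its highest other split gave 920 and 7 splits gave more than 3 times the real count. The cause of these high counts was not tested. With the array series as a block the real count was 33 and with the chip as a fixed block 43.

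The splits move single arrays as if exchangeable, although arrays of 1 chip correlate (0.483), so they say nothing of chip or array series. Against such splits chance can be excluded for the main counts as well, each being matched by 1 of 100 splits, the real one. The real count and the highest other were 13121 and 8838 for the embryonic change, 8672 and 4754 for the perinatal change and 3645 and 1586 for the postnatal change. They were 17730 and 7384 for age in C57BL/6J, 15973 and 5544 for age in DBA/2J, and 4534 and 931 for the strain difference. For the number of lists called in the changes over age at the preset correlation the splits decide nothing, so chance is neither excluded nor shown. With 3 arrays per strain and age, every split leaves part of the real age difference within each strain. The other splits called a median of 5 lists for the embryonic, 1 for the perinatal and 5 for the postnatal change. The 9 lists of the embryonic change were matched by 16 splits (highest other 12), the 3 of the perinatal change by 32 (highest other 8) and the 10 of the postnatal change by 11 (highest other 11). For the strain difference 0 lists were called (highest other 9), which all 100 splits match by construction, so nothing was tested there.

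The 3 doubted arrays, labelled DBA/2J, lay near or toward C57BL/6J. A weak strain difference at those ages is argued against, because the other DBA/2J arrays of E12 and E13 lay at 0.85 or above, and a chip effect in E13 replicate 3, because those on its chip lay at 1.06 or above; for the other 2, which share a chip with 0 other DBA/2J arrays, a chip effect stays open, and a swap with a C57BL/6J array is argued against by the highest C57BL/6J position of 0.11. In E12 replicate 2, 17 probes that are bright at P6 and P9 and dark at E12 to E14 were examined. Their median signal was 18.1% of the P6 and P9 level, against at most 0.592% on the other 14 arrays of E12 to E14. A candidate explanation is RNA of a P6 or P9 cerebellum in that array. Both doubted E13 arrays had at most -0.296%, which argues against it there. The chip of E12 replicate 2 and E13 replicate 2 also held C57BL/6J P9 replicate 2 and C57BL/6J E13 replicate 3. Where such RNA would come from was not tested. C57BL/6J RNA was tested by the positions from probes higher and from probes lower in DBA/2J. They were -0.06 and 0 in E13 replicate 3, and 0.65 and 0.57 in E12 replicate 2. In E13 replicate 2 they were 0.61 and 0.35, a gap of 0.26 that misses the bound of 0.25 set beforehand. Among the other arrays the gap reached 0.22. Mixing computed on the signal scale gives such a gap (0.67 and 0.37 at 40% C57BL/6J signal). The positions of 0.41 and 0.59 lie outside the C57BL/6J range of -0.11 to 0.11. This argues against a wrong label alone in E13 replicate 2 and E12 replicate 2, where mixing stays open. In E13 replicate 3, at -0.02 and within that range, a wrong label stays open. The computed mixing gave a position of 0.37 at 50% C57BL/6J signal and higher ones below that share. Mixing at 50% or less is thus argued against there, while a larger C57BL/6J share was not computed and stays open. A biological difference within the strain stays open and untested.

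The strain differences contained 191 probes at least 2-fold lower in DBA/2J and 52 at least 2-fold higher. Probes are usually designed on C57BL/6J sequence, so variants under a probe may lower its DBA/2J signal without a change in the transcript. The test of this, by the sign of another probe of the same gene, decides nothing: the share with the same sign was 12.8 percentage points lower for genes called lower than for genes called higher (-12.8), but genes without a called probe have a balance of signs that alone would give -22.6. Under scaling to equal medians the difference was 8.75 points, in the other direction. Variants under probes, a probe-specific difference between the separately deposited tables and a biological difference between the strains all stay open.

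The perinatal change may in part reflect the array series, since E18 and P0 shared no series or chip. With the series as a block the median ratio of the changes was 0.62, which lies between the bounds set for and against that explanation, and the count went from 8672 to 4192. The design keeps it open, because the block is estimated through other ages only. Within the series-blocked fit the microglia list (adjusted p = 5.56e-05) and the meninges list (0.00358) passed and the Bergmann glia list did not (0.26), but with an estimated correlation neither passed (0.408 and 0.458). A change at birth itself stays open for the genes that passed with the block, among them Aqp4, Dcn and Foxp2.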

How the results depend on the processing

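Array weights, blocks, filters and scalings were planned; the fit without the 3 doubted arrays was chosen only after the data were seen.

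Offset 16, normexp, the trend with robust moderation, the deposited score matrix, no filter and embryonic ages alone moved no count by over 1.5 times. Median scaling gave 609 probes for the interaction and 1 list for the strain difference. The stricter filter gave 33 and 8 probes for the strain differences in the embryonic and postnatal change. The chip as a random block gave 4094 perinatal probes and 106 and 66 for those strain differences. The chip as a fixed block gave 8027 embryonic, 2544 perinatal and 632 interaction probes, and 43 for the strain difference in the postnatal change. The array series as a block gave 8624, 4192 and, for that last difference, 33. Array weights gave 14307 perinatal, 8221 postnatal, 24038 DBA/2J age, 8222 strain and 17645 interaction probes, and 734 and 1011 for the strain differences in change; their estimation did not converge and gave 1 array a weight of 38.3, so these counts are not interpretable. With an estimated correlation 4 embryonic and 0 perinatal lists were called. The compared groups alone gave 5 perinatal lists and 4 probes for the strain difference in the postnatal change. C57BL/6J alone gave 5463 perinatal and 1996 postnatal probes, DBA/2J alone 1965 and 1323, with fewer arrays in each. Postnatal ages alone gave 2734 strain probes, also from fewer arrays. Without the 3 doubted arrays the interaction gave 2975 probes, the embryonic change 12929, the strain difference 4801 and the strain differences in change 52 and 23. The replicate block gave 13369, 9030, 3780, 18347, 16521, 4690, 1171, 57 and 21 probes, in the order of the comparisons, and 9, 3, 10 and 0 lists. It ended the call of Gli2 in the perinatal change (adjusted p = 0.0512) and changed no other call on the named genes. Of 29 same-numbered pairs across the strains 12 correlated over 0.1 (mean 0.109, against -0.046 for other numbers), so the numbers were not taken as pairs. The cause was not tested.

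Leaving out each array in turn gave 12076 to 13484 embryonic, 7301 to 9080 perinatal and 3017 to 3836 postnatal probes, 17010 to 18441 for age in C57BL/6J, 14957 to 16870 for age in DBA/2J and 4127 to 4921 for the strain difference. The interaction gave 698 (without C57BL/6J E17 replicate 1) to 1537, the strain difference in the embryonic change 31 (without DBA/2J E12 replicate 2) to 72 and that in the postnatal change 13 to 25. Lists numbered 9 to 11, 3 to 4, 7 to 10 and 0 to 1 (1 without DBA/2J E12 replicate 1 or 3).

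Of 260 results on named genes 12 turned sign with the chip as a fixed block, all in the perinatal change and none past the test there, among them Tuba1a 0.01, Huwe1 0.17, Ccnb1 0.38, Tpx2 0.21, Sox2 -0.14, Neurod1 0.17, Eomes 0.12, Nsg2 0.01, Syn2 -0.02, Hoxb3 -0.01 and Kdm5d 0.13. With the series as a block 4 did: Sox2 -0.01, Tlx3 -0.02, Syn2 -0.22 and Tyrp1 0.09. In embryonic ages alone Gjd2 turned to -0.21 in the strain difference. The cause was not tested. A further 55 and 42 no longer passed with these blocks.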

Other observations

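The test of RNA from an embryonic sample in a P9 array was chosen only after the value was seen.

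Genes of the choroid plexus, which secretes cerebrospinal fluid, were partly measured in these dissections. Of 11 measured members 5 rose and 1 fell from E12 to E18 (5 and 1 when adjusted over the list alone; list adjusted p = 0.114, but 0.0314 in the compared groups alone), with Calml4 up by 1.52 ± 0.18 and the homeobox gene Otx2 by 1.45 ± 0.18. From P0 to P6 3 rose and 2 fell (4 and 3 over the list alone; adjusted p = 0.468), with the transthyretin gene Ttr up by 2.52 ± 0.54 and Clic6 by 0.82 ± 0.16; in the compared groups alone neither passed (adjusted p = 0.115 and 0.0936). Of 11 SHH signalling genes 5 rose and 4 fell in the embryonic change (5 and 5 over the list alone; adjusted p = 0.862), with the repressor Gli3 at -2.12 ± 0.09 and the hedgehog binding gene Hhip up by 1.29 ± 0.09. Of 8 midbrain and brainstem genes 2 rose and 4 fell in the embryonic change (3 and 4 over the list alone; adjusted p = 0.437), with the motor neuron factor Isl1 at -1.95 ± 0.13. Of 4 measured caudal hindbrain Hox genes 1 fell in the embryonic change, Hoxc4 at -0.20 ± 0.07, and it did not pass with the array series as a block (adjusted p = 0.721). Of the 4 measured sex-linked genes Xist gave -1.01 ± 0.75 there (adjusted p = 0.273). From E18 to P0 the Y-linked Kdm5d changed by -0.78 ± 0.29 (adjusted p = 0.0323; 0.13 with the chip as a fixed block), with Eif2s3y at -0.80 ± 0.53 (0.265) and Xist at 0.71 ± 0.75 (0.509). The Hox and sex-linked lists were too small for the list test.

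Counting neighbouring ages, averaged over the strains, 2541 probes changed from E12 to E13, 2005 from E13 to E14, 1097 from E14 to E15, 901 from E15 to E16, 0 from E16 to E17 in limma (1284 at an unadjusted p under 0.05) and 573 from E17 to E18. With the array series as a block 326 changed from E15 to E16, 20 from E16 to E17 and 6 from E17 to E18. From birth, 4534 changed from P0 to P3 and 3478 from P3 to P6.

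On the array of C57BL/6J P9 replicate 3 the median signal at probes that are bright at E12 to E14 and dark at P6 and P9 was 9.48% of the early level, against -0.541% to 0.602% on the other 9 arrays of P6 and P9. The P9 arrays of C57BL/6J enter its age test, the late reference level and the shared estimate of spread.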
